A study of Vibrio natriegens NBRC 15636 = ATCC 14048 = DSM 759 with 12 samples.

How the data were processed

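Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on Vibrio natriegens, a marine bacterium, with an antibody against a 6-histidine tag, per the labels' protocols. In the tagged strain (NWH071) the nitrogen regulator NtrC carries the tag at its C terminus, and in the control strain (NWH061) NtrC has no tag. In both strains, per the labels, the native ntrBC genes are deleted and ntrBC under the glnA promoter replace the dns gene. Cultures were grown without oxygen at 30 °C on 25 mM glucose with either 10 mM NH4Cl or a headspace of 100% N2 as the nitrogen source. For each library 5 cultures of 10 mL were pooled at an OD660 of 0.3 to 0.5, and 2 mL samples were taken for whole-genome sequencing, which serves as the input. The remainder was crosslinked with 1% formaldehyde for 30 min, per the labels' protocols.

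There were 12 libraries, 6 from ChIP and 6 inputs. The tagged strain had 2 replicates per nitrogen source and the untagged strain 1. Each ChIP library was paired with the input of the same strain, nitrogen source and replicate number. Paired-end reads from a NextSeq2000 were mapped to the genome of the species with CLC Genomics Workbench by the authors, per the labels' protocols, which give no version and do not say how duplicate reads were handled. The deposited values are read coverage at each base of chromosome 1 (3248023 bp) and chromosome 2 (1927130 bp). They are whole numbers with no sign of scaling to depth, although the labels' protocols describe a normalization by total reads for plotting. The number of reads per library is not given, so no counting interval was computed for shares of coverage.

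Gene positions and symbols came from the RefSeq copy of the assembly named in the labels, and coordinates count from 1 on that assembly. The table held no strand, product name or sequence. For that reason the planned windows upstream of gene starts were replaced by windows at both ends of each gene, from 300 bp outside to 50 bp inside, called the low end and the high end by coordinate. There were 9379 such windows on 4690 genes. Gene lists were matched by symbol, except that transfer RNA genes were taken by gene type and ribosomal genes by gene type and the rps, rpl and rpm symbols, a rule set after the table was seen. The planned search for NtrC and sigma-54 sequence sites was not run. In this table dns is endA, ntrB is glnL and ntrC is glnG, while glnK, amtB and rpoN are not among its symbols.

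Each library was divided by its mean coverage over both chromosomes. The measure was log2((ChIP + 0.05)/(input + 0.05)) of mean coverage in 100-bp bins, and 7 bins with an input under 0.2 of the genome mean were left out, leaving 51746. Group means for the 4 ChIP groups were fitted with limma 3.58.1 in R 4.3.3, with a trend for bins and windows and none for regions, and p-values were adjusted by Benjamini-Hochberg. The fit has 2 residual degrees of freedom, both from the tagged replicates, and an untagged library is assumed to vary as they do. The prior degrees of freedom were infinite for bins and windows and 4.1 for regions. Bin and window p-values and SEs therefore rest on the trend alone and do not measure the replicate spread of a single bin or window. A bin was enriched at an adjusted p under 0.05, a tagged minus untagged difference of at least 1 (log2) and a log2(ChIP/input) of at least 1 in both tagged replicates. Enriched bins up to 200 bp apart were merged and regions of at least 200 bp kept. Changes with the nitrogen source were tested on the mean log2(ChIP/input) of each region, and on the windows, as tagged N2 minus tagged ammonium and as the same difference minus the untagged one, called tag-specific below. An enriched window had an adjusted p under 0.05 and a difference of at least 1 (log2). Each of 16 gene lists was tested with a two-sided Fisher's exact test in 4 comparisons, adjusted over all list and comparison pairs. Folds are the ratio of ChIP to input, back-transformed from the region's mean log2 value and then averaged over replicates.

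The comparisons, thresholds, gene lists and alternatives were set before the data were examined, apart from the replacements named above. The genes named were fixed in the same way. They are the 12 strongest regions per nitrogen source, up to 8 regions and 5 windows outside the regions per direction of change, the 5 strongest untagged bins per nitrogen source, 2 to 4 members of each list, and glnA, glnL, glnG, glnB, nifA, nifL, nifH, nifD, nifK and endA whatever their values. Scaling by the mean coverage outside the regions (with a 1000-bp margin), with and without tagged N2 replicate 2, was added after the data were seen, and regions and genes named from it were chosen with their values known. The planned scaling by the median bin could not be used because the median bin of tagged N2 replicate 2 is 0.

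The calling steps were tested on simulated libraries over 51745 bins. Simulated folds multiply the background coverage of each tagged library, so they are larger than the resulting folds over input at library-mean scaling and are not on the scale of the folds given for the regions. With scaling by library mean, 0 of 50 simulated regions of 4-fold and 0 of 50 of 16-fold enrichment were recovered in either nitrogen source, against 46 (ammonium) and 33 (N2) of 50 at 64-fold and 50 of 50 in both at 256-fold. No region was called where none was simulated. The simulated bins were drawn independently from a background profile shared by all libraries, with no untagged peaks. The measured untagged libraries held 70 (ammonium) and 125 (N2) runs of bins at 2-fold or more, so this gives no rate of false calls for the data. With scaling by coverage outside the regions and without tagged N2 replicate 2, 26 (ammonium) and 11 (N2) of 50 were recovered at 4-fold and 50 of 50 at 16-fold. In the test of change, 25 of 25 regions made 4-fold higher were called under scaling by library mean, and so were 43 of 73 unchanged ones, because a larger share in some regions leaves less for the others. With each tagged library centred on its median region, 25 of 25 and 0 of 73 were called. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and, in R, data.table (version 1.17.8).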

Results

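DNA bound by histidine-tagged NtrC, the response regulator that activates nitrogen stress genes together with sigma-54, was measured in Vibrio natriegens fed ammonium or only N2. The data comprise 12 libraries of read coverage. For ChIP there were 2 tagged libraries and 1 untagged library per nitrogen source, and each had its own input. Mean coverage per base in the untagged ChIP libraries was 20.6 (ammonium) and 21.0 (N2). It was 52.3 and 26.2 in tagged ammonium replicates 1 and 2, and 41.2 and 0.408 in tagged N2 replicates 1 and 2. The inputs lay between 60.5 and 73.7. In tagged N2 replicate 2, 94.4% of bases had no coverage, so outside the strongest sites it carries little information, and a log2 value near -4.2 in it means coverage of 0. The untagged groups have no replicates.

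In ammonium, 16 regions were enriched in the tagged over the untagged strain, and the strongest lay between typA, a ribosome-associated GTPase, and glnA, which encodes glutamine synthetase. This region (chromosome 1, 2787101 to 2787700, summit at 2787452) was enriched 773-fold ± 31 (SD, n = 2) over input, against 4.13-fold in the untagged library. It held 49.9% and 52.6% of all coverage in the 2 tagged libraries, against 0.166% in the untagged one. Per the labels both strains also carry a glnA promoter at dns, so this coverage may not all come from the native place. Next came a region inside PN96_RS03150 at 426-fold ± 13, the gap between PN96_RS01480 and PN96_RS01485 at 188-fold ± 21, and the gap between PN96_RS21130 and glgC at 103-fold ± 2.5 (SD, n = 2 each). The glgC gene encodes the first enzyme of glycogen synthesis, and the other 4 of these genes have no symbol in the gene table. The untagged library gave 2.63-fold, 2.51-fold and 2.22-fold at these 3 regions.

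Regions in ammonium also lay beside the native place of the ntrBC genes. Per the labels these genes are deleted there in both strains and sit at dns. Coverage within glnL and glnG is therefore given at their place in the assembly. The gap between PN96_RS12935 and glnL, the gene of the sensor kinase NtrB, was enriched 39.9-fold ± 0.060, and the gap between glnG, the gene of NtrC, and gepA 43.9-fold ± 4.07 (SD, n = 2 each). The glnG/gepA region stands apart in shape: coverage in the 3 deeper tagged libraries rose within 1 base by at least 73.4-fold (with 1 added to each value), against at most 1.12-fold in the other 15 regions. The 16 regions should therefore not be read as a count of separate binding sites. The other regions lay in the alr/dgcN gap (48.0-fold), the PN96_RS19750/PN96_RS19755 gap (35.3-fold), gabT (32.7-fold), the PN96_RS10875/PN96_RS10880 gap (26.5-fold), the xdhA/PN96_RS17835 gap (21.0-fold), the PN96_RS06640/PN96_RS06645 gap (20.8-fold), the gbdR/PN96_RS22695 gap (19.1-fold), the PN96_RS05910/PN96_RS05915 gap (17.3-fold), PN96_RS03795 (17.2-fold) and PN96_RS12920 (11.1-fold). Among them gabT encodes an aminotransferase for 4-aminobutyrate, xdhA a subunit of xanthine dehydrogenase, alr alanine racemase, and gbdR a regulator of glycine betaine breakdown. Of the 16 regions 12 had their summit between genes and 4 within a gene. The 16 regions cover 6200 bp, 0.120% of the genome, and held 75.1% and 81.5% of coverage in the tagged ammonium libraries against 0.369% in the untagged one. The tagged minus untagged difference was past the threshold in limma in every one of the 16 (adjusted p from 1.2e-06 to 0.00027). This adds no separate support, because the regions were chosen for that difference in the same libraries.

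The folds depend on the scaling, since mean coverage outside the regions was 12.9 and 4.75 in tagged ammonium and 9.63 and 0.0737 in tagged N2, well below the library means. Scaled by it, the highest typA/glnA bin went from 12.06 and 12.14 to 14.08 and 14.60 (log2) in tagged ammonium, with 3.58 untagged in both scalings. The number of regions depends on the settings as well. The count was 4 without limma's trend, 25 with a pseudocount of 0.01 and 39 without either tagged N2 library, and when regions were called anew all 16 were found in 12 of 19 settings and as few as 4 in the others.

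**Figure D1:**
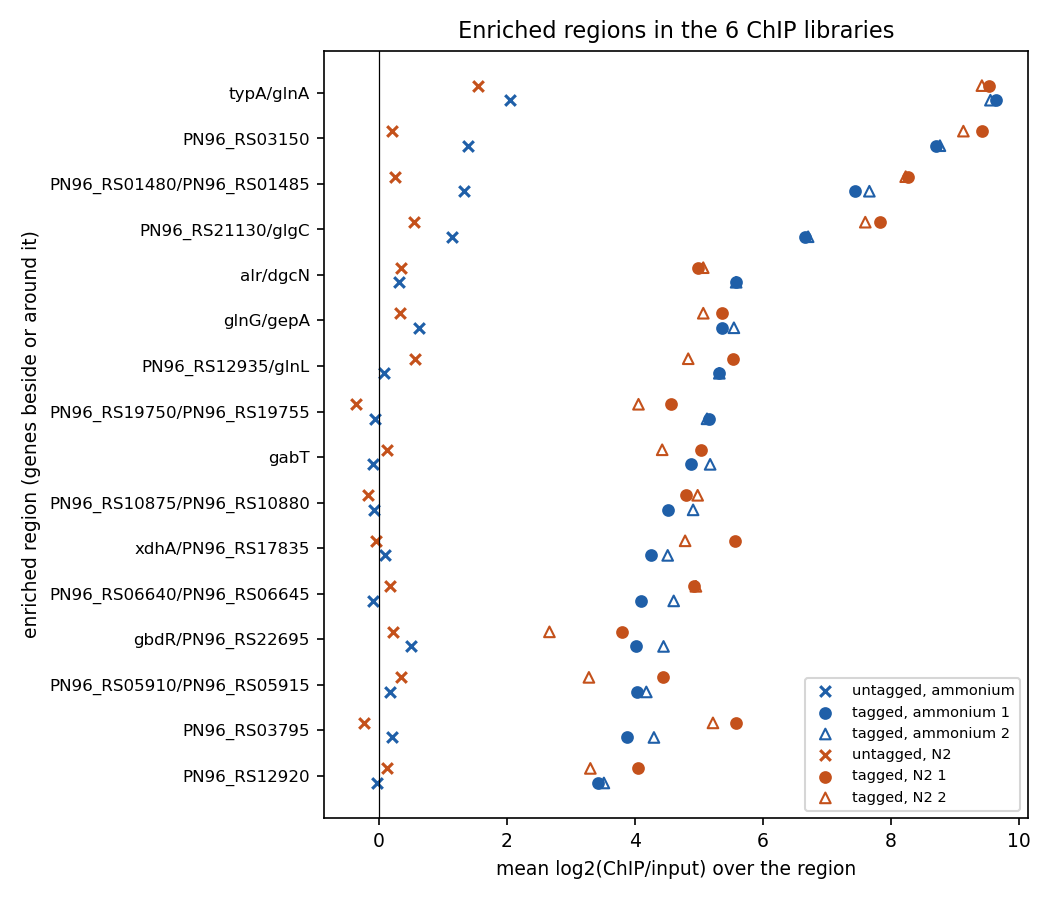
Mean log2(ChIP/input) over each of the 16 enriched regions (x axis) for each of the 6 ChIP libraries, with regions named by the genes beside or around them (y axis). Crosses are untagged libraries, filled circles replicate 1 and open triangles replicate 2 of the tagged strain, in blue for ammonium and orange for N2; the typA/glnA region stands highest at 9.63 and 9.55 in ammonium and 9.53 and 9.42 in N2.

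With N2 as the nitrogen source, 15 regions were enriched in the tagged strain, all of them among the 16 seen in ammonium. The typA/glnA region again led at 713-fold ± 40 (SD, n = 2), against 2.92-fold in the untagged N2 library, and held 40.0% and 45.3% of coverage. PN96_RS03150 followed at 623-fold ± 89, the PN96_RS01480/PN96_RS01485 gap at 304-fold ± 4.87 and the PN96_RS21130/glgC gap at 210-fold ± 23.0, with 1.16-fold, 1.20-fold and 1.47-fold in the untagged library. The gaps beside glnL and glnG stood at 37.5-fold ± 12.6 and 37.3-fold ± 5.33. Between 42.5-fold (PN96_RS03795) and 13.2-fold (PN96_RS12920) lay PN96_RS03795, xdhA/PN96_RS17835 (37.4-fold), alr/dgcN (32.7-fold), PN96_RS06640/PN96_RS06645 (30.6-fold), PN96_RS10875/PN96_RS10880 (29.8-fold), gabT (27.2-fold), PN96_RS19750/PN96_RS19755 (20.1-fold), PN96_RS05910/PN96_RS05915 (15.7-fold) and PN96_RS12920. The gbdR/PN96_RS22695 gap, at 10.2-fold ± 5.39, did not meet the bin criteria in N2, although its tagged minus untagged difference of 3.0 (log2) had an adjusted p of 0.00086 in limma. The 16 regions held 76.1% and 81.6% of coverage in tagged N2 and 0.240% in untagged N2. The count of regions in N2 was 4 without limma's trend, 36 without tagged N2 replicate 2 and 163 without tagged N2 replicate 1, where the shallow library stands alone.

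**Figure D2:**
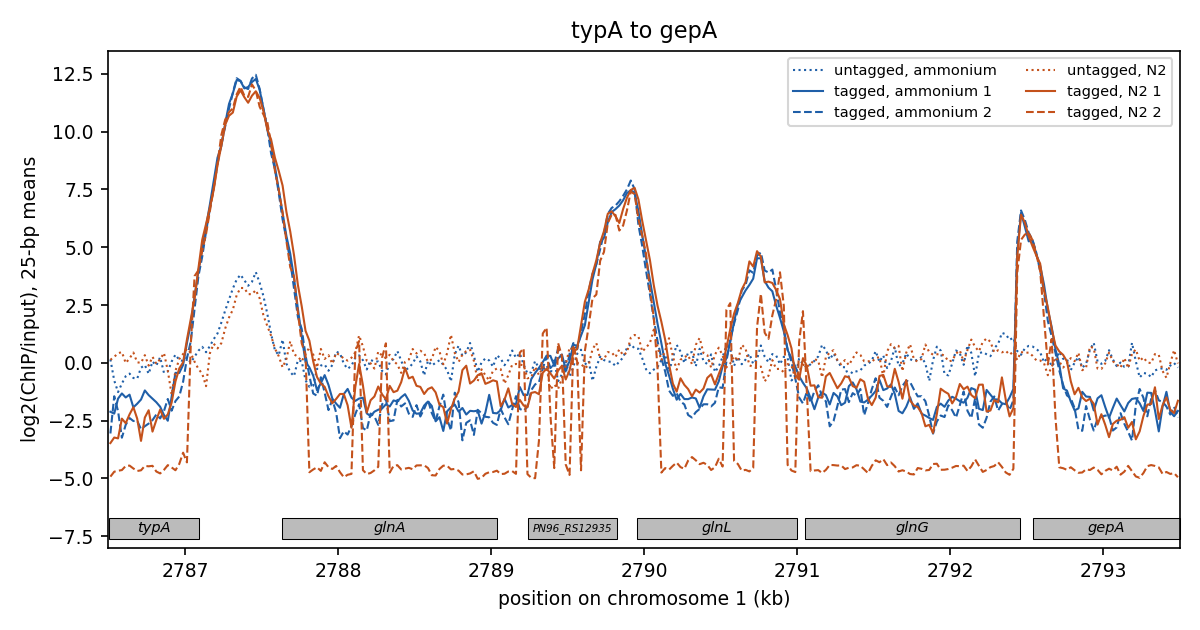
log2(ChIP/input) in means of 25 bp (y axis) along chromosome 1 from typA to gepA (x axis, kb), with a line per ChIP library and gray boxes for genes; values near -4.6 are stretches where tagged N2 replicate 2 had no coverage. Peaks stand between typA and glnA, between PN96_RS12935 and glnL, within glnL and between glnG and gepA. Genes are drawn as in the assembly, while per the labels native glnL and glnG are deleted and ntrBC sit at dns.

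Between nitrogen sources, most tagged regions differed by less than 1 on the log2 scale. The region in PN96_RS03795 rose by 1.31 ± 0.26 (log2, SE) in N2, from 17.2-fold ± 3.56 to 42.5-fold ± 7.38, and the PN96_RS21130/glgC gap rose by 1.03 ± 0.22, from 103-fold ± 2.50 to 210-fold ± 23.0 (n = 2 per group, adjusted p = 0.0248 for each in limma, with both N2 replicates above both ammonium replicates). No region fell in limma, and 7 of the 16 had an unadjusted p under 0.05. The typA/glnA region differed by -0.12 ± 0.21 (adjusted p = 0.643), the PN96_RS12935/glnL gap by -0.13 ± 0.29 (adjusted p = 0.660) and the glnG/gepA gap by -0.24 ± 0.23 (adjusted p = 0.498). After subtraction of the untagged difference, 4 regions rose in N2: PN96_RS01480/PN96_RS01485 by 1.77 ± 0.38, PN96_RS03795 by 1.74 ± 0.45, PN96_RS03150 by 1.72 ± 0.39 and PN96_RS21130/glgC by 1.63 ± 0.38 (log2, SE; limma, adjusted p = 0.0257, 0.0329, 0.0257 and 0.0257). Part of these values comes from the single untagged libraries, whose own N2 minus ammonium difference was -1.07, -0.43, -1.18 and -0.60 at these regions.

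When each tagged library was centred on its median region, 9 regions changed. The 6 higher in N2 were PN96_RS03795 (1.31), PN96_RS21130/glgC (1.03), xdhA/PN96_RS17835 (0.79), PN96_RS01480/PN96_RS01485 (0.70), PN96_RS06640/PN96_RS06645 (0.58) and PN96_RS03150 (0.54), with adjusted p from 0.0045 to 0.0487. The 3 lower were the gbdR/PN96_RS22695 gap (-1.0), the PN96_RS19750/PN96_RS19755 gap (-0.83) and the alr/dgcN gap (-0.55), with adjusted p from 0.0180 to 0.0450 in limma. Centring hardly moved the differences and lowered the SEs, at PN96_RS01480/PN96_RS01485 from 0.218 to 0.168. The offsets come from these same 16 regions and were not counted in the degrees of freedom, so the added calls are weak. The regions held similar shares of coverage in tagged ammonium (75.1% and 81.5%) and tagged N2 (76.1% and 81.6%), unlike in the simulation. The PN96_RS03795 call was lost without any 1 of the 4 tagged libraries and the PN96_RS21130/glgC call without either tagged ammonium library, with a replicate block (adjusted p = 0.0854) and with scaling by coverage outside the regions (0.0680), with values on these intervals from 1.1 to 1.53 and from 0.92 to 1.14 over 20 settings and adjusted p up to 0.469 and 0.507. The 4 tag-specific calls were all lost without either tagged ammonium library, with a replicate block (adjusted p from 0.0885 to 0.0888) and with scaling by coverage outside the regions (0.0643 to 0.0669).

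**Figure D3:**
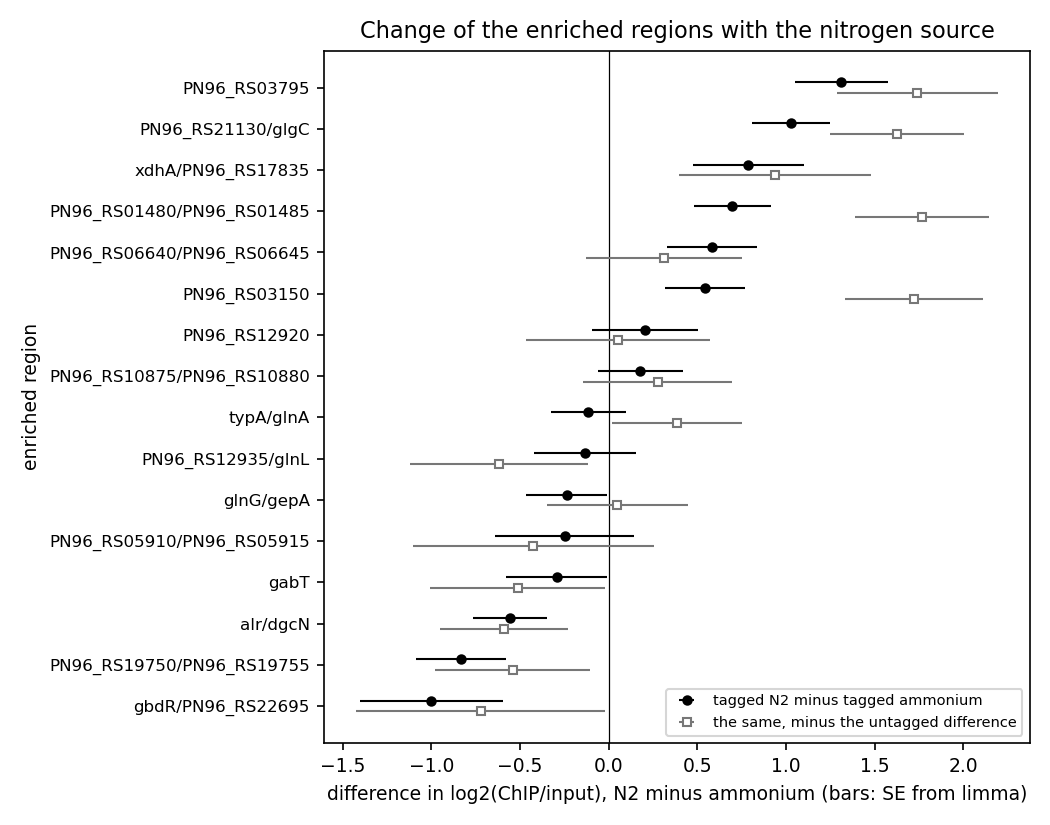
Difference in mean log2(ChIP/input) between N2 and ammonium (x axis) for each of the 16 regions (y axis). Filled circles are tagged N2 minus tagged ammonium and open squares the same minus the untagged difference, with bars of 1 SE from limma. Among the filled circles PN96_RS03795 stands highest at 1.31 and the gbdR/PN96_RS22695 gap lowest at -1.0. Among the open squares PN96_RS01480/PN96_RS01485 stands highest at 1.77.

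At gene ends, 48 windows of 46 genes were enriched in ammonium and 43 windows of 41 genes in N2, and 26 of each overlapped a region. The window at the low end of glnA stood at 11.36 and 11.45 in tagged ammonium and 11.04 and 11.14 in tagged N2 (log2), and that at the low end of glnL at 6.54, 6.63, 6.44 and 5.99. A further window, 2790751 to 2791100, lay outside the 16 regions at the low end of glnG, but its signal is that of a peak inside glnL, and log2(ChIP/input) over the bases of glnG in this window was below 0 in both tagged ammonium libraries. It stood at 2.36, 2.56, 2.66 and 1.78, against 0.09 and -0.25 untagged (adjusted p = 3.2e-09 and 5.5e-10 in limma). The median window read -1.88 and -2.25 in tagged ammonium and -2.01 and -4.26 in tagged N2, against 0.01 and -0.03 untagged, which puts the median difference from untagged at -2.07 (ammonium) and -3.00 (N2), and windows near these values do not stand out from the rest. Such were the windows of glnB, the gene of a PII protein, at -2.44 and -2.00 in ammonium, of nifA at -2.17 and -2.41, and of nifH, the gene of nitrogenase reductase, at -2.18 and -1.31 (low and high end). In N2 these stood at -1.97 and -3.86 (glnB), -3.12 and -2.61 (nifA) and -3.03 and -2.66 (nifH), and the windows of endA, an endonuclease gene, at -1.67 and -2.15 in ammonium and -3.18 and -0.98 in N2. The simulation covered the bin and region steps and not the windows, so it gives no limit for window calls. In it, regions with 16 times the background coverage of their own library were not recovered at this scaling. That fold over background is not on the scale of the folds over input above.

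Among the 16 gene lists only nitrogen signalling passed. In it 3 of 7 genes, glnA, glnL and glnG, were enriched in each nitrogen source (two-sided Fisher's exact test, odds ratio 80.2 in ammonium and 90.7 in N2, adjusted p = 0.00096 for both), and 3 when adjusted over the list alone. These 3 genes lie close together in the assembly, so they are not independent. Per the labels glnL and glnG are deleted from this place in both strains. The stronger glnG window is that of the glnG/gepA region with its 1-base rise. The low-end window of glnG was carried by the peak inside glnL, so neither window is separate evidence for glnG. The test rests on the scaling: with scaling by coverage outside the regions 2 of 7 were called, with an adjusted p of 0.138 in both sources, and over 15 settings the adjusted p ran from 0.00029 to 0.189.

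In the other lists the enriched members were glnA for ammonium assimilation (1 of 6, adjusted p = 0.694 by Fisher's exact test in both sources) and glnG for sigma-54 activators (1 of 8, adjusted p = 0.694). In nitrogen fixation, with scaling by library mean and all libraries kept, 0 of 12 genes were called in any of the 4 comparisons, also when adjusted over the list alone. The high end of nifL, a nif regulator, came nearest at -0.58 (ammonium) and -0.35 (N2) relative to untagged, above the medians of all windows, while nifD stood at -1.93 and -1.01 (high end) and nifK at -2.04 and -1.51 (low end). No gene was called in either source in the lists for nitrate and nitrite use (6 genes), alternative nitrogen sources (18), flagella and chemotaxis (31), biofilm (1), ribosomal genes (88), transfer RNA (129), ATP synthase and core energy (14), translation factors and chaperones (13), housekeeping controls (11), fermentation (15), molybdenum and iron supply (15) and electron supply to nitrogenase (9). These counts cover gene ends alone, so the region inside gabT, a member of the alternative nitrogen sources, is not among them. The lowest unadjusted p among these by Fisher's exact test was 0.629. Adjusted over the list alone, 1 fermentation gene passed for the change between nitrogen sources and 1 sigma-54 activator for the tag-specific change, and in the lists with 0 genes called for enrichment the count stayed at 0. In the same order, tagged minus untagged in ammonium and in N2 (log2) was as follows, at the end of each gene with the higher value in either source. Among genes of nitrogen use, motility and biofilm stood napA (-2.46 and -0.53), nirB (-1.85 and -1.31), oppC (-2.19 and -0.50), gabT (-0.81 and -1.11), fliE (-1.75 and -0.67), flhA (-1.99 and -1.24) and vpsR (-1.41 and -1.59). Among genes of ribosomes, transfer RNA, energy, translation and housekeeping stood rpsU (0.09 and -0.66), rpmF (-1.68 and -0.38), PN96_RS00690 (-1.96 and -0.85), PN96_RS00685 (-1.92 and -0.88), atpA (-1.92 and -0.40), atpE (-1.75 and -0.85), groL (-2.61 and -1.16), tuf (-1.66 and -1.25), dnaA (0.11 and -1.36) and rpoB (-2.35 and -0.59), where rpsU and rpmF are ribosomal genes, groL a chaperone gene and dnaA the gene of the replication initiator. Among metabolic genes stood adhE (-1.54 and -0.11), focA (-1.72 and -0.41), modA (-2.10 and -0.77), moaE (-1.33 and -1.20), rsxB (-1.74 and -1.60) and fldA (-2.10 and -1.81), of which modA belongs to a molybdate transporter and fldA to the flavodoxins.

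Of the windows, 5 rose and 12 fell from ammonium to N2 in limma, and 0 of these 17 overlapped an enriched region. This balance rests on the setting. Rises outnumbered falls with scaling by coverage outside the regions and without tagged N2 replicate 2. Among the 12, the largest falls were at the high end of mioC (-3.20) and the low end of mnmG, a transfer RNA modification gene (-3.13), which overlap. There the replicates were far apart: mioC read 2.62 and -1.52 in tagged ammonium and -0.65 and -4.65 in tagged N2. The SE of 0.48 for mioC comes from the trend and does not carry this spread. Next were PN96_RS24410 (-2.83), PN96_RS21975 (-2.76) and PN96_RS21980 (-2.66), each with tagged N2 replicate 2 near -4.2. The highest rises were PN96_RS17030 (1.65), PN96_RS04140 (1.63), PN96_RS17025 (1.59), PN96_RS03700 (1.58) and the low end of dgcN (1.52). At dgcN the tagged values went from 0.38 and 0.33 to 2.77 and 0.98. At the other 4 the untagged N2 library also read high, from 1.92 to 2.50. Among sigma-54 activators norR, a regulator of nitric oxide detoxification, was called at -2.54 (1 of 8 genes, Fisher's exact test adjusted p = 0.611), with tagged N2 replicate 1 at 0.96 and replicate 2 at -4.36. The count was 0 without limma's trend, 0 with a pseudocount of 0.2 and 0 without tagged ammonium replicate 1, and 8113 without tagged N2 replicate 1, where the shallow library stands alone.

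In the tag-specific comparison of windows, 0 rose and 2 fell, mioC (-5.43) and mnmG (-5.39), with 8 and 18 windows at an unadjusted p under 0.05 in limma. Both calls were lost without tagged ammonium replicate 1 and without limma's trend. Tagged N2 replicate 2, with little or no coverage there, read -4.65 and -4.57. In the untagged strain alone 0 windows rose and 0 fell in limma between nitrogen sources, with 5 and 3 at an unadjusted p under 0.05. This sets 1 library against 1, with the spread taken from the tagged replicates, so it says little about the untagged strain. The strongest untagged signals in ammonium were at typA/glnA (11.9-fold in the highest bin), PN96_RS01480/PN96_RS01485 (7.52-fold), PN96_RS03150 (5.99-fold), PN96_RS18810/PN96_RS18815 (4.91-fold) and PN96_RS21130/glgC (4.49-fold). In N2 they were at mioC/mnmG (22-fold), PN96_RS03700/PN96_RS03705 (8.53-fold), PN96_RS18810/PN96_RS18815 (8.19-fold), typA/glnA (7.91-fold) and PN96_RS17025/PN96_RS17030 (7.28-fold). Runs of bins at 2-fold or more numbered 70 in untagged ammonium and 125 in untagged N2.

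With scaling by coverage outside the regions, the nif genes could be read at lower enrichment. The stretch from nifH to modC (chromosome 2, 971735 to 988599), which holds the nitrogenase genes and a molybdate transporter, stood at -0.14 and -0.22 in tagged ammonium and 0.81 in tagged N2 replicate 1 (log2). The untagged libraries went from 0.00 in ammonium to 0.37 in N2, and tagged N2 replicate 2, with a coverage of 0.0737 outside the regions, stood at -0.60. Next to it, the gap between rarD and PN96_RS19540 (990101 to 990500) held a peak of 16.1-fold ± 4.80 (SD, n = 2) in tagged ammonium and a log2 value of 3.38 in tagged N2 replicate 1, against 0.06 and -0.25 untagged. Beside the low end of nifH there was none: -0.22 and -0.60 in tagged ammonium, -0.18 in tagged N2 replicate 1, and -0.13 and -0.10 untagged.

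**Figure D4:**
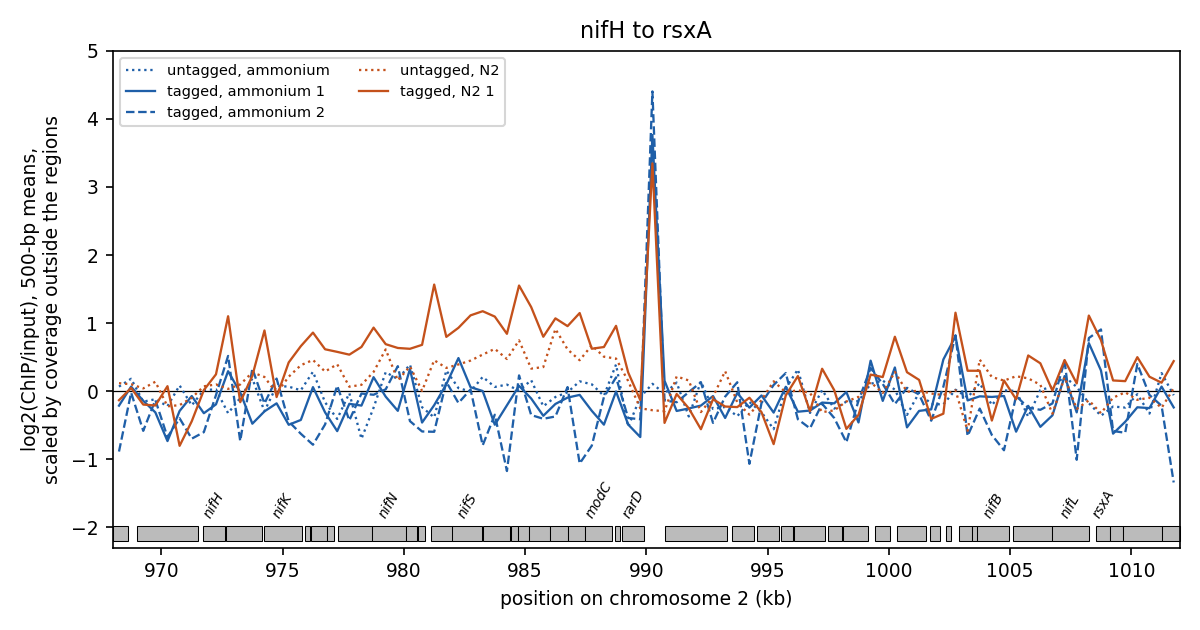
log2(ChIP/input) scaled by coverage outside the regions, in means of 500 bp (y axis), along chromosome 2 from nifH to rsxA (x axis, kb), with a line per ChIP library except the shallow tagged N2 replicate 2 and gray boxes for genes. The tagged N2 library lies above the others in most but not all means from nifH to modC (0.81 over the stretch, against 0.37 in untagged N2). All 3 tagged libraries drawn peak between rarD and PN96_RS19540.

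Input coverage departed from its surroundings at or beside some of the loci named in the labels' genotypes. The gap between typA and glnA had 2.22 ± 0.05 times the genome mean (SD, n = 6 inputs), against 1.22 ± 0.08 in typA and 1.24 ± 0.08 in glnA. The labels do not describe this gap as edited, but they also place a glnA promoter at dns. Whether coverage of that copy counts in this gap was not tested. The glnG/gepA gap likewise stood at 2.11 ± 0.13, against 1.07 ± 0.04 in glnG and 1.22 ± 0.07 in gepA, and glnL at 1.1 ± 0.06. The PN96_RS12935/glnL gap, on the other side of ntrBC, did not stand out, at 1.24 ± 0.09 against 1.20 ± 0.07 in PN96_RS12935. In endA, the dns gene of the labels, 675 bases (171352 to 172026) had a coverage of 0 in all 12 libraries. These 12 libraries include both strains, so the inputs cannot tell the tagged from the untagged strain.

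Input coverage differed along both chromosomes between a high and a low stretch. On chromosome 1 the ratio of highest to lowest (running median over 100 kb) was 1.76, 1.68 and 1.59 in the ammonium inputs and 1.36, 1.46 and 1.47 in the N2 inputs (untagged, then tagged replicates 1 and 2). On chromosome 2 it was 1.48, 1.43 and 1.37 in ammonium and 1.25, 1.29 and 1.33 in N2. Mean coverage of chromosome 2 relative to chromosome 1 was 0.860, 0.872 and 0.895 in ammonium and 0.927, 0.904 and 0.896 in N2. All 3 ammonium inputs lay above all 3 N2 inputs in the ratio on both chromosomes, but strains were mixed in each set and the difference was not tested.

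**Figure D5:**
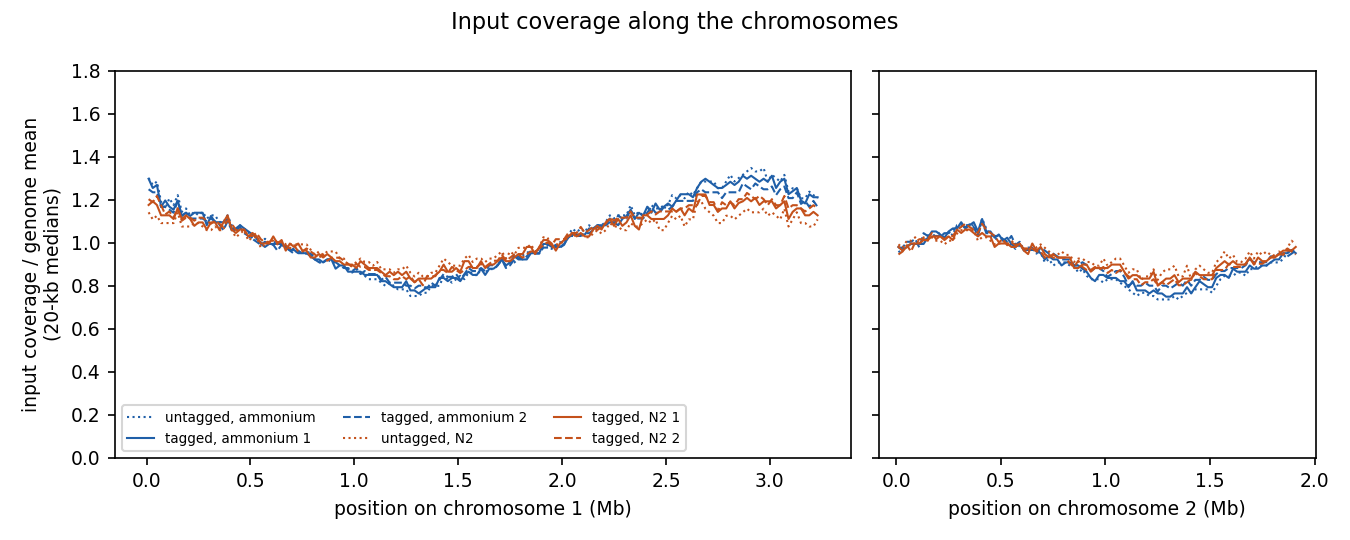
Input coverage relative to the genome mean, as medians of 20 kb (y axis), along chromosome 1 (left) and chromosome 2 (right; x axes, Mb), with a line per input library, blue for ammonium and orange for N2. The ammonium inputs span more from highest to lowest, 1.59 to 1.76 on chromosome 1, than the N2 inputs, 1.36 to 1.47.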

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

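The tests of explanations in this part were chosen after the results were seen. At 4 regions the N2 minus ammonium difference of the tagged strain was larger than that of the untagged strain in limma: PN96_RS01480/PN96_RS01485 by 1.77, PN96_RS03795 by 1.74, PN96_RS03150 by 1.72 and PN96_RS21130/glgC by 1.63 (log2), each lost without either tagged ammonium library and with a replicate block. At 2 overlapping windows it was smaller, mioC by -5.43 and mnmG by -5.39, both lost without tagged ammonium replicate 1 and without limma's trend. Tagged N2 replicate 2 read -4.65 and -4.57 in these windows, with little or no coverage, which enlarges the values. At mioC and mnmG the untagged N2 library read 3.38 and 3.72 and the untagged ammonium library 1.15 and 1.46, while the tagged ammonium replicates lay apart, at 2.62 and -1.52 for mioC.

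At 3 of the 4 regions part of the difference came from coverage in the untagged ammonium library, which is a pattern of its own: untagged coverage stood above background at the strongest tagged sites. One candidate source is carry-over of fragments from tagged libraries, which would keep the sites in the proportions of the tagged libraries. In untagged N2 the excess coverage was 146 ± 3.0 at typA/glnA, 7.35 ± 2.82 at PN96_RS01480/PN96_RS01485 and 5.58 ± 3.0 at PN96_RS03150, which gives ratios of 19.9 and 26.2. Here ± is a spread taken from the central percentiles of windows of the same length, which leaves out the tails. The 4 tagged libraries gave 3.27 to 5.53 and 2.82 to 5.19. With the typA/glnA excess lowered and the other raised by 2 such spreads each, the untagged ratios were still 10.8 and 12.1. As far as that spread holds, this argues against carry-over in these proportions. At PN96_RS21130/glgC, however, the ratio of 15.3 lay inside the tagged range of 8.41 to 21.5. In untagged ammonium the ratios were 3.89 ± 0.17, 4.89 ± 0.29 and, at PN96_RS21130/glgC, 10.7 ± 1.4, all inside the range of the 4 tagged libraries pooled. Tagged ammonium alone gave 5.17 to 5.53, 4.65 to 5.19 and 18.5 to 21.5. Tagged N2 alone gave 3.27 to 3.375, 2.82 to 3.13 and 8.41 to 11.4. Neither source alone spans all 3 untagged ratios, so the pooled range is a loose test. Carry-over from a mix of tagged libraries stays open there. Recovery of untagged NtrC by the antibody also stays open and was not tested.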

How the results depend on the processing

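Settings scaled by coverage outside the regions were added after the data were seen, and the others were planned. Called anew, all 16 ammonium and all 15 N2 regions were found in 12 of 19 settings, and as few as 4 in each. The tagged minus untagged difference on the fixed intervals passed the threshold in all settings. This says little, as the intervals were chosen for that difference in the same libraries. For the change with nitrogen source 296 region tests kept their side of the threshold, with 14 gained and 10 lost, and for the tag-specific change 277, with 1 gained and 26 lost. No called value changed sign. Depth and scaling both limit these results: tagged N2 replicate 2 has a mean coverage of 0.408 per base, and scaling alone moved the regions from 16 and 15 to 30 and 29 with that library kept. Simulated regions at 16 times background or less, a scale other than that of the folds over input, were not recovered with scaling by library mean, and the simulation that recovered them changed the scaling and left out that library together. Counts of changed and tag-specific regions below are over regions called anew. On the fixed intervals the PN96_RS03795 and PN96_RS21130/glgC changes each stayed past the threshold in 15 of 20 settings, and the tag-specific changes in 12 (PN96_RS01480/PN96_RS01485), 14 (PN96_RS03150), 10 (PN96_RS03795) and 14 (PN96_RS21130/glgC) of 19. The causes below were not tested, except that fewer libraries or another region set change what is tested.

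With a pseudocount of 0.01, regions in ammonium were 25, changed regions 0, tag-specific regions 0, changed windows 39 (16 higher, 23 lower), tag-specific windows 7 and windows changed without the tag 2. On the fixed intervals the 2 change calls (adjusted p = 0.0237 for each) and 4 tag-specific calls (0.0239 to 0.0288) were kept. With 0.2, changed regions were 5 (3 higher, 2 lower), changed windows 0, tag-specific windows 4 and windows changed without the tag 4. Without the low-input filter, changed regions were 0 and tag-specific regions 2, with fixed-interval values unchanged (0.0248 to 0.0329). With the other choice of trend, regions were 4 in ammonium and 4 in N2, windows 10 and 7, changed windows 0 and tag-specific windows 0. With 50-bp bins changed regions were 7 (4 higher, 3 lower). With 200-bp bins, regions were 29 and 24, changed regions 0 and tag-specific regions 0, while on the fixed intervals both change calls (0.0425) and 3 tag-specific calls (0.0321) were kept and the tag-specific call of PN96_RS03795 was lost (0.0810). With regions of at least 300 bp, changed regions were 4 (3 higher, 1 lower), and centred on the median region 9 (6 higher, 3 lower). With shorter windows outside the gene, changed windows were 0 and those changed without the tag 2, and with windows that end at the gene changed windows were 11 (1 higher, 10 lower).

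Replicate numbers are not known to mark a shared culture or day. Deviations of same-numbered tagged libraries had a correlation of 0.001 over regions and 0.01 over windows, so samples were not paired. With a replicate block, regions were 14 and 13, changed regions 1, tag-specific regions 4 (on the 4 fixed intervals the calls were lost, adjusted p from 0.0885 to 0.0888), windows 39 and 37, changed windows 2 (0 higher, 2 lower), tag-specific windows 4 and windows changed without the tag 2.

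Leaving out 1 tagged library at a time, where the lone replicate is assumed to vary like the other groups, regions in ammonium ran from 13 to 39, regions in N2 from 13 to 163, changed regions from 2 to 147, tag-specific regions from 0 to 138, windows from 41 to 56 in ammonium and from 40 to 70 in N2, changed windows from 0 to 8113, tag-specific windows from 0 to 6448, windows changed without the tag from 0 to 8 and gene lists past the threshold, counted as pairs of list and comparison, from 2 to 4 (2 are nitrogen signalling in each nitrogen source, and the further 2 the ribosomal and transfer RNA changes). The highest of most came without tagged N2 replicate 1, which leaves the shallow library alone. Without tagged N2 replicate 2 there were 39 and 36 regions, 4 changed (3 higher, 1 lower), 0 tag-specific (on the fixed intervals PN96_RS03150 and PN96_RS21130/glgC kept theirs, 0.0292 each), 12 changed windows and 6 tag-specific ones.

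With scaling by coverage outside the regions there were 30 and 29 regions, 1 changed (lower), 0 tag-specific (on the fixed intervals the PN96_RS03795 change was kept, 1.36 with adjusted p = 0.0197, and the PN96_RS21130/glgC change and all 4 tag-specific calls were lost), 76 and 78 windows, 27 changed (11 higher, 16 lower), 6 tag-specific and 0 gene list pairs. With that scaling and without tagged N2 replicate 2 there were 75 and 70 regions, 3 changed, 0 tag-specific (on the fixed intervals no change or tag-specific call was kept), 129 and 126 windows, 73 changed (41 higher, 32 lower), 2 changed without the tag and 2 gene list pairs, the changes in nitrogen fixation and in molybdenum and iron supply. Median instead of mean coverage gave 2.36 times the genome mean at typA/glnA, and a running median over 50 kb a ratio of 1.59 on chromosome 1. Scaling by the median bin and the tests of NtrC sequence sites were not run.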

Other observations

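The tests, genes and regions in this part were chosen after the data were seen. Scaling by coverage outside the regions, without tagged N2 replicate 2, gave 75 regions in ammonium and 70 in N2, of which 63 were shared, and all 16 regions of the report were among them. Beyond those 16, peaks stood within glnL (24.9-fold ± 7.62, SD, n = 2), at tauA/PN96_RS16305, where tauA is a gene of taurine uptake (17.7-fold ± 2.90), at rarD/PN96_RS19540 (16.1-fold ± 4.80), at PN96_RS03475/metG (15.9-fold ± 3.73), in leuA, a gene of leucine synthesis (10.4-fold ± 1.44), at norR/hcp (9.25-fold ± 0.086) and at guaD/PN96_RS19040 (8.99-fold ± 4.00), all in tagged ammonium. In tagged N2 replicate 1 these 7 stood at 4.74, 4.29, 3.38, 3.98, 3.22, 3.30 and 3.86 (log2), and in the shallow replicate 2, left out of this setting, lower at 2.3, 2.97, 1.65, 2.34, -0.60, -4.34 and 2.16. In this setting 3 regions rose in N2 in limma and 0 fell, with 14 at an unadjusted p under 0.05: PN96_RS02255/PN96_RS02260 by 1.63, PN96_RS22990/PN96_RS22995 by 1.60 and rimK/PN96_RS17105 by 1.50. The untagged libraries were higher in N2 at all 3, at 2.33 against 1.32, 0.65 against 0.10 and 2.09 against 1.36. The PN96_RS03795 and PN96_RS21130/glgC calls were not kept in this setting, at 1.37 (adjusted p = 0.0583) and 0.71 (adjusted p = 0.369) on the wider regions found there.

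The gap between nifL and rsxA (chromosome 2, 1008301 to 1008600) was called as a region only in N2 in that setting. It stood at 1.95 in tagged N2 replicate 1 and 1.85 in replicate 2 (left out of the setting), against 1.39 ± 0.50 (log2, SD, n = 2) in tagged ammonium. The untagged libraries stood at -0.26 and -0.45, and the N2 minus ammonium difference was 0.56. The window at the high end of nifL, 1008207 to 1008556, exceeded untagged in both sources, by 1.53 in ammonium and 1.95 in N2. The region call in N2 alone therefore does not mean a site bound only in N2. In that setting windows of 6 of 12 nitrogen fixation genes (nifD, nifK, nifT, nifU, nifS and nifV) and of 4 of 15 molybdenum and iron supply genes, among them modA, modB and modC, changed between nitrogen sources (Fisher's exact test, adjusted p = 3.7e-07 and 0.0015). The nif genes and modA, modB and modC are neighbours in the stretch from nifH to modC, and the tagged N2 side is a single library, so the genes are not independent and both lists rest largely on the same signal. Over the 15 settings the adjusted p ran up to 1 for both, and each passed in 1 of 15. With the untagged difference subtracted, 0 of 12 and 0 of 15 were called.

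The raised coverage from nifH to modC in N2 is the first of the patterns weighed here. The untagged N2 library exceeded untagged ammonium by 0.373 (log2), more than 99.4% of windows of that length, so a signal that does not need the tag may give part of it. These windows overlap each other and include the stretch itself, and 1 untagged library is set against 1. Such percentages are ranks and not p-values. Tagged N2 replicate 1 exceeded tagged ammonium by 0.99, which is 0.62 more than the untagged difference (above 99.0% of windows), but tagged N2 replicate 2 differed by -0.423 with a spread of 0.47 between windows, so a spread of tagged NtrC over these genes cannot be told apart from library variation, because only 1 tagged N2 library is deep enough. Gene bodies of other lists also stood higher in tagged N2 replicate 1 than in tagged ammonium, ATP synthase and core energy by 0.34, transfer RNA by 0.22 and ribosomal genes by 0.165, against untagged differences of 0.10, 0.03 and -0.02, so the rise is not particular to nif and mod genes, although it was larger in nitrogen fixation (0.61, against 0.24 untagged). A biological difference between the nitrogen sources, such as transcription of these genes in N2, stays open and was not tested, since no expression was measured.

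A second pattern is the shape of the glnG/gepA peak. In the 3 deeper tagged libraries the coverage rose within 1 base (2792440, 15 bases from the end of glnG) from 11 to 1022, 1 to 605 and 9 to 733, by at least 73.4-fold with 1 added to each value, while the largest 1-base rise in the other 15 regions was 1.12-fold. On the glnL side the largest 1-base fall was at 2789957, 3 bases into glnL, in all 3 libraries, at 1.23-fold, 1.26-fold and 1.09-fold, against up to 1.12-fold in other regions, so this side is the weaker part of the test. This argues against the locus as in the reference, which the labels' deletion of the native ntrBC genes in both strains already excludes. Fragments from the PN96_RS12935/glnL site that run across the deletion could give the rise. A bound site within the gap, beside the edge of the deletion, could give it too, since the bases to its left are missing. The step therefore cannot tell whether the gap holds a binding site of its own. No biological explanation was tested.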
